A study of Mus musculus with 16 samples.

How the data were processed

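Single-cell RNA was measured in CD45-sorted cells of 16 subcutaneous tumour samples, 4 per group. The values used were UMI counts per gene and cell, which the authors made with Cell Ranger against mm10 and handled further with Seurat per the submitters' processing notes. Versions of those tools were not given in the sources used here. The counts of CD40ICB a and b, as deposited, list 64591 features of a combined human and mouse reference, 33538 of them human, and the other 3 matrices list the 31053 mouse genes alone. Only mouse genes were used. Genes marked by a rule as possibly following the reference numbered 1 in CD40ICB a (AY036118) and 12 in b, AY036118 among them. As a and b share the reference, it alone does not account for the genes marked in b only. Gene coordinates are those of GENCODE vM21 on mm10.

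Barcodes ended in a suffix that numbered the wells of a matrix. Before the data were examined, each suffix was set to count as a replicate library if a matrix had no more suffixes than its group has samples, with edgeR's quasi-likelihood fit as the main test. CD40ICB b, with 8 suffixes, was pooled without a test, and its intervals are exact Clopper-Pearson 95% intervals that cover counting error only. CD40ICB as a whole had 12 suffixes for 4 samples, so some suffixes may share an animal and p may be too small. Sex-linked RNAs differ between CD40ICB a and b in every library, so the matrices share no animal. If the 4 samples supplied both matrices, CD40ICB a held fewer than 4 of them. Some of its suffixes then share a sample, and n = 4 overstates its replicates. The labels do not link suffixes to samples. P values measure only the spread between libraries, which may be technical.

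Of 41999 barcodes, 28206 had at least 200 genes and at most 10% mitochondrial UMIs. Scrublet called 130 of them doublets (0.461%), far fewer than the loading predicts, so it has not worked here. An added alternative, chosen after this was seen, removed 467 by an expected rate of 0.8% per 1000 cells. The 28076 cells left were clustered with scanpy 1.11.5 and leidenalg 0.10.2 on 2000 variable genes, 30 principal components and 15 neighbours at resolution 1.0, which gave 22 clusters. A cluster was named by a cell type if at least 3 of that type's fixed markers were at least 2-fold higher in it, unless another type's markers prevailed among its 10 top genes. The classes are marker-based, hence neutrophil-like, T-like and monocyte/macrophage-like. T and monocyte/macrophage clusters were clustered again for subsets. Sub-clusters with markers of another lineage were set apart as mixed, left out of gene tests, and held 18.4% of T-like cells in untreated, 19.6% with ICB, 13.3% with CD40, 13.5% in CD40ICB a and 4.63% of pooled b. In the monocyte/macrophage class they held 2.69%, 5.23%, 8.69%, 4.42% and 21.9%.

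UMIs of a class were summed per library with at least 10 of its cells. The sums ran from 45137 to 2316765 UMIs in neutrophil-like, 173407 to 2157075 in monocyte/macrophage-like and 78463 to 9135483 in T-like cells, with common biological coefficients of variation of 0.252, 0.247 and 0.192. T-like sums came from 2 untreated, 4 ICB, 4 CD40 and 3 CD40ICB a libraries, and monocyte/macrophage-like sums from 4, 4, 3 and 4. All groups were fitted together with edgeR 4.0.16 in R 4.3.3, with TMM scaling, edgeR's expression filter and 2-sided quasi-likelihood tests, adjusted by Benjamini-Hochberg over the genes of a class, at 0.05. DESeq2 1.42.0 was the other tool. The mean log2 TMM factor differed from that of untreated by more than 0.1 in neutrophil-like cells with ICB (0.105) and in T-like cells of CD40ICB a (-0.138). A higher factor lowers the folds. CPM means and SD are per library. Values in parentheses after a gene are its edgeR log2 fold ± SE and its adjusted p, unless summed counts are named.

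Shares were tested with exact 2-sided permutation over libraries and with edgeR, adjusted over 11 lineages, 7 T subsets or 4 monocyte/macrophage subsets per comparison. Fixed gene lists, 23 in number and some sharing genes, were tested with camera from limma 3.58.1 at a preset correlation of 0.01 and again with the correlation estimated from the data. A list needed at least 4 measured members. Counts of a list adjusted over the list alone use its members' p only. Summed-count lists were ranked among 10000 random lists of genes of like level.

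Genes were named by a rule. In each of the 3 largest classes the 4 largest rises and 4 largest falls in summed-count CPM with 10 added were taken, among genes of at least 50 CPM in either set, at least 20 counts over both and a counting interval that excludes no change. For CD40ICB the smaller change of both matrices was used. Ribosomal, mitochondrial, haemoglobin, immunoglobulin, receptor segment, sex-linked and predicted genes were left out. Pdcd1, Ctla4, Cd40, Cd274 and Cd40lg were always named where they could be tested, and members of the fixed lists serve as examples. Other genes in the text were chosen after their values were seen.

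The edgeR fit was tested on simulated data, with 200 genes of the CD40 against untreated design given a known fold. It found 59% of true log2 folds of 1 and 93% of 2 in neutrophil-like cells, 46% and 94% in monocyte/macrophage-like cells and 44% and 96% in T-like cells, with 10 of 162, 12 of 152 and 7 of 146 calls false. Alternatives changed the cell filter, doublet removal, clustering, subset rule, scaling, gene filter, pseudocount, depth and test, and left out each library in turn. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.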

Results

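Immune cells sorted on CD45 were profiled by droplet single-cell RNA sequencing from subcutaneous tumours that C57BL/6J mice carried after injection of a pancreatic ductal adenocarcinoma line derived from the KPC mouse model. Tumours were left for 14 days before treatment, and cells were taken 12 days after treatment began. The 16 samples formed 4 groups of 4: untreated, ICB (antibodies against PD-1 and CTLA-4, checkpoint receptors that restrain T cells), CD40 (an agonist of CD40, a receptor through which T cells activate antigen-presenting cells) and CD40ICB (the agonist with both antibodies). Counts came in 5 matrices, 1 for each of the first 3 groups and 2 for CD40ICB, called CD40ICB a and CD40ICB b here. Barcode suffixes separated 4 libraries in each matrix except b, which held 8, more than the group has samples. Suffixes of b were therefore pooled and their values carry no test. The matrices summed to 42478581 UMIs for untreated, 76311277 for ICB, 37971613 for CD40, 12386337 for CD40ICB a and 40832501 for CD40ICB b. After filtering, 3557, 4581, 4868, 1357 and 13713 cells were kept in that order, with 2536, 3112, 3883.5, 2744 and 2059 UMIs per cell at the median.

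Summed over all libraries, those of b included, neutrophil-like, T-like and monocyte/macrophage-like cells were the largest immune classes. The comparison of their shares asks how each treatment altered the make-up of the tumour's immune cells. Monocyte/macrophage-like cells made up 22.6% ± 12.1 of untreated cells (SD, n = 4 libraries), 19.8% ± 3.63 with ICB, 8.63% ± 4.25 with CD40 and 7.95% ± 1.81 in CD40ICB a. Exact 2-sided permutation gave p = 0.0571 for CD40 and 0.0286 for CD40ICB a, the smallest that 4 against 4 libraries allow. T-like cells made up 4.64% ± 4.04 of untreated cells, 7.52% ± 2.40 with ICB, 23.7% ± 27.6 with CD40 and 20.6% ± 27.6 in CD40ICB a. Their exact permutation p were 0.286, 0.0857 and 0.229. Neutrophil-like cells made up 18.4% ± 10.0 of untreated cells, 26.9% ± 6.42 with ICB, 36.1% ± 16.6 with CD40 and 21.8% ± 16.7 in CD40ICB a (exact permutation p = 0.229, 0.171 and 0.8). Of the pooled cells of CD40ICB b, 64.92% were neutrophil-like (exact 95% interval 64.11 to 65.72), 23.96% T-like (23.24 to 24.68) and 5.22% monocyte/macrophage-like. A tumour-like epithelial cluster held 9.74%, 15.7%, 4.35% and 9.73% of cells in the first 4 sets and 0.00729% in b, which is 1 cell. A cluster of tumour and red-cell transcripts held 19.8%, 9.18%, 11.0% and 24.4%, and 0.0292% in b. A cluster led by Mmp12 and Arg1, genes of tissue-remodelling macrophages, got no name and lies outside the monocyte/macrophage-like class. It held 17.9%, 15.5%, 11.6% and 11.3%, and 1.57% in b, so in untreated and ICB it was larger than the T-like class. None of the 11 lineage shares passed edgeR's test after Benjamini-Hochberg adjustment against untreated. The T-like share gave log2 2.35 ± 1.01 (SE, adjusted p = 0.185) with CD40 and 2.13 ± 1.004 (0.141) in CD40ICB a. The monocyte/macrophage-like share gave -1.38 ± 0.51 (0.167) and -1.51 ± 0.51 (0.0582). Replicate 4 of CD40 held 65.0% T-like cells and replicate 4 of CD40ICB a 61.5%, and without them the T-like share gave log2 1.09 and 0.57. With each library clustered on its own the monocyte/macrophage-like share gave 0.66 with CD40 and 0.51 in CD40ICB a, and the T-like share of CD40ICB a -0.66. With non-immune cells left out both shares of CD40ICB a were past the threshold (T-like 2.004, monocyte/macrophage-like -1.31).

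**Figure D1:**
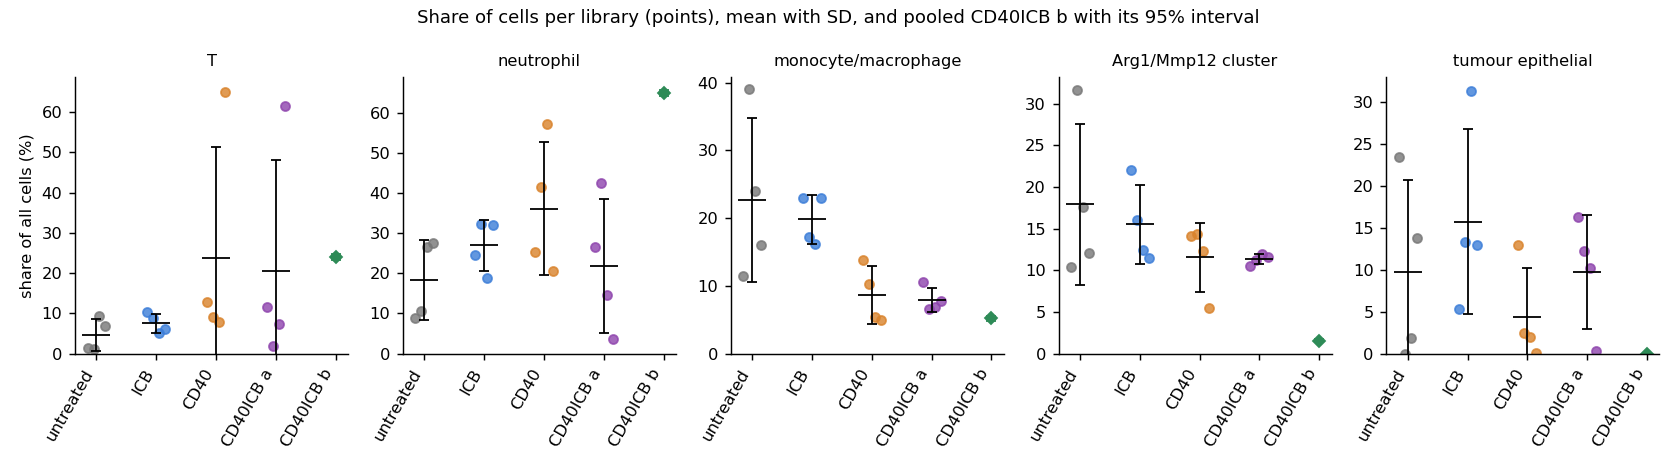
Share of all kept cells (%) in 5 classes, with 1 point per library, the mean and SD as horizontal line and bars, and the pooled CD40ICB b as a diamond with its 95% interval. Monocyte/macrophage-like shares lie at 22.6% in untreated and 7.95% in CD40ICB a on average, and 1 library each of CD40 and CD40ICB a exceeds 60% T-like cells.

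Xist, the RNA that silences an X chromosome in female cells, and Y-linked genes differed between groups and not within them. In neutrophil-like cells Xist lay at 0 to 8.51 CPM over the untreated libraries and 0 to 10.1 over those of CD40ICB a, against 347 to 505 with ICB, 447 to 581 with CD40 and 400 to 871 over the wells of b. The Y-linked Eif2s3y lay at 60.9 to 86.6 CPM in untreated, 43.9 to 88.6 in CD40ICB a and at most 0.432 in the other sets. ICB and CD40 therefore each differ from untreated in these markers as well as in treatment, and CD40ICB a differs from ICB and from CD40. The comparisons of CD40 with ICB and of CD40ICB a with untreated do not. Counts of genes past the threshold are given with and without sex-linked genes, here Xist, Tsix and Y-linked genes. Other genes on chromosome X, such as Cxcr3, stay in the counts. CD40ICB a and b differ in these markers in every library and so share no animal. If the samples of the group supplied both matrices, the libraries of a outnumber its samples, and its tests count too many replicates. The labels do not show how the samples were divided.

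Checkpoint antibodies alone were compared with no treatment to ask what they changed in each immune class. In neutrophil-like cells no gene other than sex-linked ones passed edgeR's quasi-likelihood test at an adjusted p under 0.05 (4 genes in all, Xist, Tsix, Eif2s3y and Ddx3y, 182 at an unadjusted p under 0.05, 5 with DESeq2). Gbp4, a guanylate-binding protein induced by interferon-gamma, had 10.2 ± 7.66 CPM with ICB and 3.24 ± 3.9 without (SD, n = 4 and 4, log2 0.68 ± 0.62). H2-K1, a classical MHC class I heavy chain, had 545 ± 84.9 and 421 ± 216 (0.16 ± 0.34). The largest differences in summed counts were in Ccl5, a chemokine (1.81 ± 1.71), the chemokine receptor Cx3cr1 (1.19 ± 0.56), Rgs1 (0.86 ± 0.33) and AW112010 (0.63 ± 0.59) on the higher side. Lower were the acute-phase gene Saa3 (-3.50 ± 1.43), Gadd45g (-2.42 ± 0.52, adjusted p = 0.377), Lcn2 (-1.86 ± 0.66) and the heat-shock gene Hspa1b (-1.47 ± 0.68). Over fits without 1 library Ccl5 ran from -1.07 to 4.05 and Saa3 from -4.72 to 1.38, so 1 library sets their direction. Cd274, which encodes the PD-1 ligand PD-L1, gave -0.47 ± 0.41. Of 23 hypoxia and glycolysis genes 0 passed the test over all genes and 0 adjusted over the list alone, with a median of -0.43 (camera with a preset correlation, adjusted p = 2.24e-06, adjusted p = 0.94 with an estimated correlation).

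Monocyte/macrophage-like and T-like cells also gave no gene past the threshold with ICB other than sex-linked ones. The monocyte/macrophage-like cells gave 5 in all (176 at an unadjusted p under 0.05, DESeq2 5). The count was 3 without any one of untreated replicates 1, 3 or 4 or ICB replicates 1, 3 or 4. In them Retnla, a marker of alternative activation, gave log2 4.12 ± 1.69, the granzyme Gzma -5.63 ± 2.30 (-9.53 to 5.47 over fits without 1 library), the interferon-induced chemokine Cxcl10 -2.44 ± 1.18, and Ccl7 -1.58 ± 1.27. Values were 2.23 ± 0.77 for Ctla4, -0.19 ± 0.44 for Cd40, 0.13 ± 0.35 for Cd274 and -0.14 ± 0.23 for Apoe, and none of these genes passed. The mast-cell proteases Mcpt1, Mcpt2 and Cma2 and the granzyme Gzmf led the ranking by summed counts and were too sparse per library to be tested. Of 7 lists past the threshold with a preset correlation none held with an estimated one. The median of the interferon-gamma response genes was -0.18 (adjusted p = 0.767 with an estimated correlation). In T-like cells 4 sex-linked genes passed (192 at an unadjusted p under 0.05, DESeq2 3), and 7 without untreated replicate 3 or 4. The gamma-delta receptor gene Trdc gave 2.20 ± 1.18, Cd163l1, found on gamma-delta T cells, 2.35 ± 0.95 and Ccl1 2.33 ± 1.57. Cst3 gave -1.74 ± 0.50, Xcl1 -1.48 ± 1.33, Gzmc -1.23 ± 1.24 and Sfn -1.87 ± 0.75, and with 1 library left out at most -0.15, 1.70, 1.91 and -0.24. The targeted receptor genes gave 0.18 ± 0.28 for Pdcd1 and 0.44 ± 0.26 for Ctla4, and Cd40lg, the ligand of CD40, 0.30 ± 0.70. Regulatory T-like cells made up 28.3% ± 14.5 of untreated T-like cells (n = 2 libraries of at least 10 T-like cells) and 29.7% ± 10.7 with ICB (n = 4, edgeR log2 0.05 ± 0.56, adjusted p = 0.927).

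The CD40 agonist was compared with no treatment to ask how activating CD40 altered tumour-infiltrating myeloid and T-like cells. Neutrophil-like cells of CD40-treated tumours carried more interferon-induced and antigen-presentation transcripts. Gbp4 (Ensembl gene ENSMUSG00000079363, mm10 chromosome 5, 105115767 to 105139586, minus strand) rose from 3.24 ± 3.9 to 80.3 ± 36.8 CPM (SD, n = 4 and 4, edgeR log2 3.66 ± 0.51 SE, adjusted p = 0.000474). H2-K1 rose from 421 ± 216 to 1834 ± 422 (1.98 ± 0.35, 0.00324). Of 24 measured interferon-gamma response genes 17 rose and none fell. Adjusted over the list alone 23 rose, and their median was 1.91 (camera adjusted p = 2.12e-52, adjusted p = 0.0024 with an estimated correlation). Among them was Cxcl9, a chemokine that attracts CXCR3-bearing T cells (2.64 ± 0.49, 0.0103). Others were Socs1, a feedback inhibitor of cytokine signalling (1.91 ± 0.39, 0.0195), Nlrc5, the activator of MHC class I genes (2.65 ± 0.57, 0.029), and Zbp1 (1.91 ± 0.37, 0.0108). Gbp2 (3.06 ± 0.67, 0.0494), Gbp5 (2.44 ± 0.47, 0.0129) and Ifi47 (3.18 ± 0.50, 0.00324), which overlaps Olfr56, have close relatives or neighbours, so the copy that gave their UMIs is uncertain.

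Of 18 MHC class I presentation genes in the same cells 9 rose and none fell. Adjusted over the list alone 13 rose, and the median was 1.26 (camera adjusted p = 2.93e-24, adjusted p = 0.0024 with an estimated correlation). Tap1, which carries peptides into the endoplasmic reticulum, gave 1.61 ± 0.31 (adjusted p = 0.00959). B2m, the MHC class I light chain, gave 1.34 ± 0.33 (0.0494), and H2-D1 1.32 ± 0.35 (0.080). H2-Q4 (2.37 ± 0.32), H2-Q6 (3.80 ± 0.83) and H2-Q7 (3.20 ± 0.51) rose as well but are near-identical copies. The same holds for Ly6a (3.53 ± 0.46) and Ly6i (4.42 ± 0.92, adjusted p = 0.0400, lost in 11 of 16 fits without 1 library, the highest 0.213). Of 19 type I interferon genes 3 rose, Xaf1 (1.91 ± 0.43), Irf7 (1.57 ± 0.38) and Ifit1 (2.77 ± 0.62), and 14 rose when adjusted over the list alone. Their median of 1.17 was past the threshold with a preset correlation (6.56e-15) but not with an estimated one (adjusted p = 0.189). Of 12 C1q and resident macrophage genes Selenop fell by 2.07 ± 0.45 (adjusted p = 0.0377, lost in 9 of 16 fits without 1 library, the highest 0.162). Adjusted over the list alone 4 fell, and the median was -1.10 (adjusted p = 0.398 with an estimated correlation). Fcrls, Cd72 and the Notch target Hes1 fell by 2.23 ± 0.48, 2.06 ± 0.45 and 2.30 ± 0.49. C1qa, a macrophage marker, had 449 CPM in these droplets in untreated and 218 with CD40, against 3045 in monocyte/macrophage-like cells with CD40. Whether the falls of macrophage genes here come from less macrophage RNA in the droplets was not tested. Apoe (-1.98 ± 0.74, adjusted p = 0.398), Ccl12 (-2.51 ± 0.64, 0.0885) and Lcn2 (-1.60 ± 0.66, 0.478) did not pass. Nor did Ccl5 (4.18 ± 1.78, 0.520) and Cd274 (0.75 ± 0.41, 0.680). In all 45 genes that are not sex-linked rose and 6 fell of 6509 tested (71 genes with DESeq2, sex-linked ones included, against 55 with edgeR). The count of 55 was 35 and 19 without untreated replicates 1 and 4, and 27 and 33 without CD40 replicates 3 and 4. It was 84 without CD40ICB a replicate 3. Clusters 6 and 11, led by Siglecf and by Cebpe and Prtn3, held 51.5% and 24.1% of the class in untreated and 38.1% and 41.2% with CD40.

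**Figure D2:**
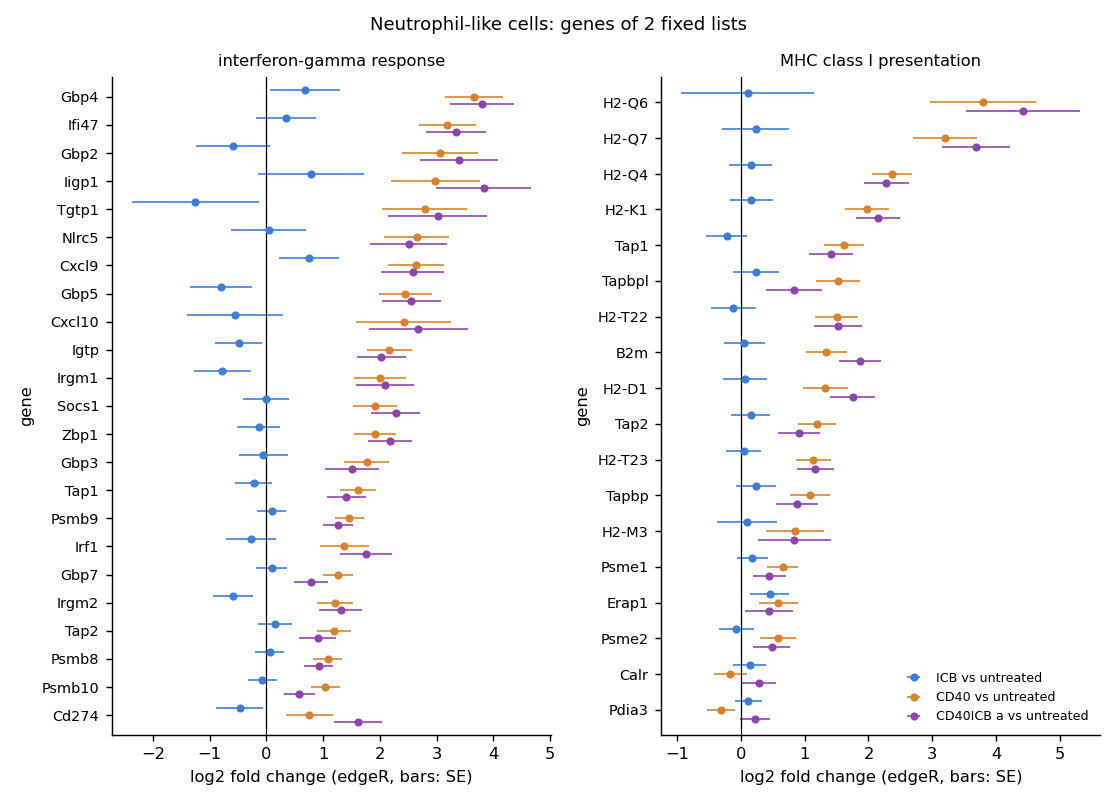
Log2 fold change against untreated (edgeR, bars are SE) of interferon-gamma response genes and MHC class I presentation genes in neutrophil-like cells, for ICB, CD40 and CD40ICB a. CD40 and CD40ICB a lie to the right of 0 for every interferon-gamma gene shown, and ICB scatters about 0.

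CD40 treatment went with more Pdcd1lg2, which encodes PD-L2, in monocyte/macrophage-like cells (14.2 ± 4.78 CPM in untreated, n = 4, and 44.5 ± 8.02 with CD40, n = 3, log2 1.60 ± 0.30, adjusted p = 0.0297). Sod2, a mitochondrial superoxide dismutase (1.17 ± 0.22, 0.0297), Il1rn, the interleukin-1 receptor antagonist (1.44 ± 0.27, 0.0351), and H2-Q6, whose copy is uncertain (2.77 ± 0.50, 0.0256), also rose. Cd72 (-1.72 ± 0.30) and Tanc2 (-1.94 ± 0.33) fell. The macrophage subset, whose markers include Apoe and C1q genes, fell from 23.6% ± 2.05 to 11.2% ± 2.89 of the class (n = 4 and 4, exact permutation p = 0.0286, the smallest possible, edgeR log2 -0.99 ± 0.14, adjusted p = 3.88e-05). With ICB it made up 27.6% (0.0286 as well, edgeR adjusted p = 0.319). With Leiden resolution 0.5 the CD40 difference was -0.0114. Sub-clusters without a name held 70.9% of the class in untreated and 77.8% with CD40. Its share and the level of its genes are not independent. Apoe gave -1.16 ± 0.25 (adjusted p = 0.0814) and C1qb -0.62 ± 0.22 (0.464). Of 27 interferon-gamma response genes 1 rose, 17 when adjusted over the list alone, with a median of 1.02 (camera adjusted p = 1.39e-20, adjusted p = 0.0813 with an estimated correlation). Of 18 MHC class I genes H2-Q6 rose, 8 when adjusted over the list alone (median 0.54, adjusted p = 0.0668 with an estimated correlation). Of 7 checkpoint genes Pdcd1lg2 rose, 3 adjusted over the list alone (median 1.23, camera adjusted p = 4.23e-09, adjusted p = 0.0183 with an estimated correlation). The 15 C1q and resident macrophage genes had a median of -0.62, with none past the threshold and 6 lower when adjusted over the list alone (0.0915 with an estimated correlation).

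Genes ranked by summed counts in this class did not pass. Upp1 gave 2.03 ± 0.53 (adjusted p = 0.227), Ccl5 2.12 ± 0.56 (0.254), the arginine-synthesis enzyme Ass1 2.496 ± 0.73 (0.353) and Acod1, which makes itaconate, 1.90 ± 0.65 (0.483). Gzma gave -5.31 ± 2.66 (0.841, and up to 5.79 with 1 library left out), Fcrls -2.64 ± 0.65 (0.198) and Cx3cr1 -1.91 ± 0.39 (0.0814). Cd274 gave 1.23 ± 0.37 (0.313), Cd40 0.57 ± 0.47 (0.958), Ctla4 1.69 ± 0.88 (0.847), and Nos2, the inducible nitric oxide synthase, 2.53 ± 0.91 (0.554). Apart from sex-linked genes 5 rose and 2 fell of 8106 tested (10 called with sex-linked genes, 43 with DESeq2). The count of 10 was 5 and 6 without untreated replicates 1 and 4 and 6 without ICB replicate 2 or 4. It was 4 without CD40 replicate 4 and 17 without CD40ICB a replicate 4. A cluster led by Apoe and C1qa held 60.6% of the class in untreated and 36.2% with CD40. A cluster led by Chil3 and Lyz2 held 14.9% and 38.1%, and a cluster led by histone genes 24.6% and 25.7%.

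T-like cells of CD40-treated tumours held a lower share of regulatory cells and more transcripts of the chemokine receptor Cxcr3 (ENSMUSG00000050232, mm10 chromosome X, 101731535 to 101734269, minus strand), which guides T cells to interferon-induced chemokines. Cxcr3 rose from 29.1 ± 6.65 CPM in untreated (n = 2) to 171 ± 25.1 with CD40 (n = 4, log2 2.60 ± 0.30, adjusted p = 1.82e-06). As Cxcr3 is X-linked and both groups differ in sex markers, the size of this rise may not reflect treatment alone. It also rose in CD40 against ICB, alike in these markers. Regulatory T-like cells fell from 28.3% ± 14.5 to 8.47% ± 4.36 of T-like cells (edgeR log2 -1.87 ± 0.60, adjusted p = 0.0124, not past the threshold at -1.22 without untreated replicate 4 and -1.44 without CD40 replicate 4). Exact 2-sided permutation gave p = 0.133, the smallest that 2 against 4 libraries allow. Pooled over all kept cells, with CD40 replicate 4 giving most T-like cells, they numbered 54 of 3557 in untreated and 99 of 4868 with CD40. The fall is thus one of their share among T-like cells. Ikzf2 and Ikzf4, transcription factors of these cells, fell, and their levels are not independent of the share. Ikzf2 (ENSMUSG00000025997, chromosome 1, 69531214 to 69687245, minus strand) fell from 634 ± 174 to 223 ± 85 CPM (-1.48 ± 0.29, 0.0113) and Ikzf4 from 115 ± 16 to 17.7 ± 7.1 (-3.11 ± 0.31, 1.68e-07). Foxp3, their lineage factor, gave -1.25 ± 0.58 (adjusted p = 0.458) and Il2ra, the high-affinity interleukin-2 receptor chain, -1.13 ± 0.40 (0.258). Of 12 regulatory T genes Itgae and Ikzf2 fell, the same number adjusted over the list alone (median -0.73, adjusted p = 0.191 with an estimated correlation). Of 10 T helper 1 genes Cxcr3 rose, 1 adjusted over the list alone (median 0.65, adjusted p = 0.063 with an estimated correlation). Of 28 proliferation genes none passed, 1 lower adjusted over the list alone (median -1.17, adjusted p = 0.526 with an estimated correlation).

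Also higher in the T-like cells were Slamf6, a receptor of memory-like T cells (1.55 ± 0.34, 0.0152), the co-stimulatory receptor Cd28 (1.30 ± 0.31, 0.0364), Btg2 (1.19 ± 0.29, 0.0317) and Dusp2 (1.942 ± 0.36, 0.00939). Tsc22d3, Klrb1b and Ret rose too (for Ret 4.11 ± 0.79, 0.00443, and 0.137 at most without untreated replicate 3 or 4). Itgae, an integrin of tissue-resident cells (-2.505 ± 0.45, 0.0113), Cd244 (-4.13 ± 0.56, 8.36e-05), Igfbp4 and the DNA methyltransferase Dnmt3a were lower. AC163354.1 was lower too (-3.02 ± 0.52, 0.0113, and 0.142 at most without untreated replicate 3 or CD40 replicate 4). Pdcd1 (0.49 ± 0.27, 0.540), Ctla4 (0.19 ± 0.26), Cd40lg (1.48 ± 0.61, 0.341) and Cd274 (-0.21 ± 0.34) did not pass. Neither did Csf2 (3.55 ± 2.17, 0.637), Zfp36l2 (1.93 ± 0.52, 0.118), Gzmc (-7.36 ± 2.03, 0.138) and Gzma (-4.23 ± 1.42, 0.260). CD8 T-like cells made up 31.7% of untreated T-like cells and 53.3% ± 13.2 with CD40 (log2 0.78 ± 0.56, 0.292, but past the threshold at 3.58 with a higher Leiden resolution and at 2.96 with doublets kept). The subset held different cells in each group, 48 of 62 in untreated from a sub-cluster led by Gzmc and Gzma and 1249 of 1337 with CD40 from one led by Ret and Gzmk. The Gzmc sub-cluster met 8 CD8 T markers and also held the NK marker Klre1 beside Cd8a among its top genes. Cd244 is another of its top genes, so the level of Cd244 is not independent of this sub-cluster. CD4 conventional T-like cells made up 1.69% and 15.3% (2.73 ± 0.90, 0.0124), a difference that turned to -0.27 when cells were assigned by their own UMIs and to -0.14 with Leiden resolution 0.5. Without untreated replicate 4 it was 1.71 (adjusted p = 0.421). Of 6098 genes tested 40 that are not sex-linked rose and 49 fell (94 called with sex-linked genes, 58 with DESeq2). The count of 94 was 44 and 62 without untreated replicates 3 and 4, leaving 1 untreated library assumed to vary like the rest, and 32 without CD40 replicate 4, the library with 65.0% T-like cells. CD40 replicate 4 gave 1743 of the 1991 T-like cells of CD40 before mixed sub-clusters were left out, and 1822 were left after. In the pooled cells left, the cluster led by CD8 genes held 36.9% of the class in untreated and 76.0% with CD40. The Foxp3 cluster held 33.8% and 4.88%.

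**Figure D3:**
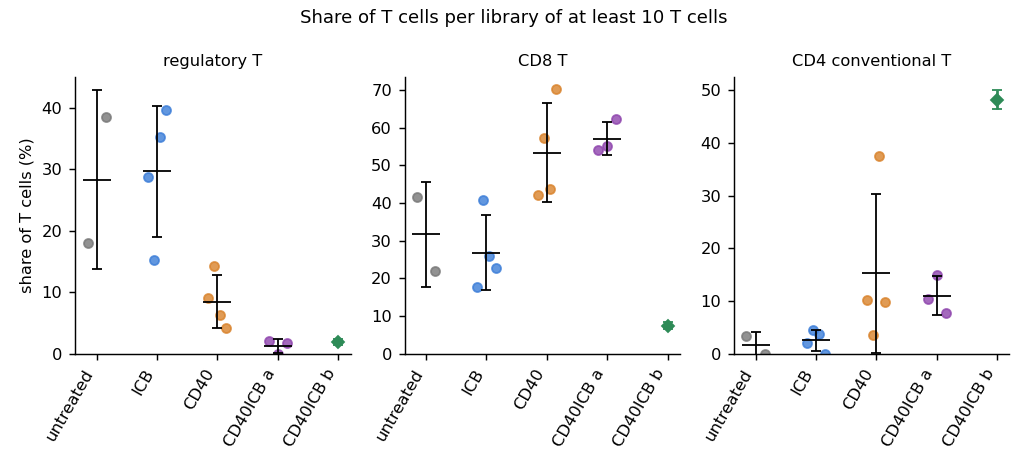
Share of T-like cells (%) assigned to regulatory, CD8 and CD4 conventional subsets, with 1 point per library of at least 10 T-like cells, mean and SD, and the pooled CD40ICB b with its 95% interval. Regulatory shares average 28.3% in untreated, 29.7% with ICB, 8.47% with CD40 and 1.30% in CD40ICB a.

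The combination was compared with no treatment in CD40ICB a by test, with the pooled CD40ICB b beside it. In neutrophil-like cells of CD40ICB a the interferon-gamma response again rose. Gbp4 reached 75.7 ± 21.3 CPM (n = 4 libraries, which may hold fewer samples, log2 3.80 ± 0.56, adjusted p = 0.00189) and H2-K1 1911 ± 297 (2.15 ± 0.35, 0.00274). Isg15, a ubiquitin-like type I interferon product, reached 1289.8 ± 421 against 300.0 ± 59.9 in untreated (2.16 ± 0.37, 0.00405). Of 24 interferon-gamma response genes 11 rose, all 24 when adjusted over the list alone (median 2.06, camera adjusted p = 9.38e-46, adjusted p = 0.00159 with an estimated correlation). Of 18 MHC class I genes 6 rose and 11 adjusted over the list alone (median 1.04, adjusted p = 0.00159 with an estimated correlation). Of 19 type I interferon genes 3 rose and 17 adjusted over the list alone (median 1.87, adjusted p = 0.0496 with an estimated correlation). Of 13 mitochondrially encoded RNAs mt-Nd3 fell by 1.35 ± 0.29. Adjusted over the list alone 11 fell, and the median was -0.86 (0.065 with an estimated correlation). Cxcl9 (2.58 ± 0.56, 0.0319), Socs1 (2.28, 0.0122), H2-D1 (1.75 ± 0.36, 0.0176), B2m (1.87 ± 0.33, 0.00562) and Irf7 (2.05 ± 0.41, 0.0176) rose. So did Bst2, which tethers virions (1.53 ± 0.28, 0.00562), the lipid-droplet coat gene Plin2 (1.53 ± 0.36, 0.0495), Pycard, the inflammasome adaptor (1.29 ± 0.27, 0.0235), and Nupr1 (2.92 ± 0.56, 0.0122). Ifi47, H2-Q4, H2-Q7, Ly6a and Ly6i, whose copies are uncertain, rose as well (for Ly6i 5.09 ± 0.96, adjusted p = 0.0235, lost in 7 of 16 fits without 1 library, at most 0.19). Ccl2, a monocyte chemoattractant (4.67 ± 1.11, 0.107), Cd274 (1.61 ± 0.43, 0.108), and Rcan1 (-2.21 ± 0.65, 0.190) did not pass. Neither did Retnlg (-1.24 ± 0.68, 0.588), Sycp2 (-1.58 ± 0.42, 0.0945) and H2-Eb1 (-1.53 ± 0.71, 0.4999). In all 38 genes rose and 2 fell apart from AY036118, whose level may follow the gene reference (41 called with it, 75 with DESeq2). The count of 41 was 22 and 18 without untreated replicates 1 and 4, and 66, 22, 23 and 27 without CD40ICB a replicates 1 to 4. It was 27 with at least 20 cells per library. Of 35 ways to split these 8 libraries evenly, another gave 52 genes.

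In the pooled neutrophil-like cells of CD40ICB b the same list stood higher still, with a median of 2.64 in summed counts (percentile 100 among 10000 random lists, 1.31 in CD40ICB a and 1.501 with CD40 by the same measure). Cd274 (ENSMUSG00000016496, mm10 chromosome 19, 29367455 to 29388095, plus strand) had 2103 CPM (95% counting interval 2081 to 2125) against 283 in untreated, Gbp4 294, Ifi47 569, Ccl2 441 and Isg15 2401. Type I interferon (median 1.88), MHC class I (1.67) and chemokine genes (1.28) lay at percentile 100. Lists at percentile 0 were MHC class II (-3.13), C1q (-2.33) and mitochondrially encoded genes (-2.54). For C1q genes, a part of macrophage RNA in the droplets was not tested. Rcan1 (log2 -1.80), Retnlg (-1.88), Sycp2 (-2.50) and H2-Eb1 (-3.74) were lower. Of 3018 genes compared, 363 were at least 2-fold higher and 618 at least 2-fold lower than in untreated, beyond counting error and with no replicate check. The neutrophil-like cells of b lay in other clusters than the rest. Of them 31.0%, 29.5% and 28.8% lay in clusters led by Gdf15 and Hilpda, by Rsad2, Ifit1 and Isg15, and by Il23a, Tnf and Ccl2. The Siglecf cluster held 55.6% for CD40ICB a.

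Monocyte/macrophage-like cells of CD40ICB a carried less of the lipid-transport gene Apoe and the complement gene C1qb. Apoe (ENSMUSG00000002985, mm10 chromosome 7, 19696109 to 19699188, minus strand) fell from 21116 ± 4624 to 7013 ± 1619 CPM (n = 4 and 4, log2 -1.59 ± 0.23, adjusted p = 0.00362). C1qb (ENSMUSG00000036905, chromosome 4, 136880129 to 136886187, minus strand) fell from 3797 ± 736 to 1941 ± 534 (-0.97 ± 0.21, 0.0430). H2-K1 (1.04 ± 0.16, 0.00362), H2-D1 (0.84 ± 0.15, 0.0167) and Sod2 (1.39 ± 0.21, 0.00362) rose. So did Gpr84, a receptor for medium-chain fatty acids (2.22 ± 0.43, 0.0279), Dram1 (1.77 ± 0.27, 0.00362), Mdm2 and Prdx6. The receptor kinase Axl (-0.84 ± 0.19, 0.0463), the MHC class II chaperone Cd74 (-1.07 ± 0.23, 0.0430), Mgl2 (-1.39 ± 0.30, 0.0430), Cd72 and Tmem176b fell. Zmynd15 fell as well (-2.17 ± 0.43, 0.0416, lost in 10 of 15 fits without 1 library, at most 0.0935). The macrophage subset fell to 6.62% ± 1.90 of the class (exact permutation p = 0.0286, edgeR log2 -1.67 ± 0.27, adjusted p = 0.000402). It gave 0.58 with Leiden resolution 0.5 and was 0.559% in b. T-cell transcripts rose in the same droplets, Bcl11b by log2 3.71 ± 0.61, Cd28 by 4.45 ± 0.76 and Lck by 2.76 ± 0.54. Sub-clusters with markers of another lineage had been left out and made up 2.69% of the class in untreated and 4.42% in CD40ICB a.

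Of 27 interferon-gamma response genes in these cells 1 rose, 15 when adjusted over the list alone (median 1.15, adjusted p = 0.113 with an estimated correlation). Of 18 MHC class I genes 5 rose, 7 higher and 1 lower adjusted over the list alone (median 0.46, adjusted p = 0.087 with an estimated correlation). Of 8 MHC class II genes Cd74 fell, 6 adjusted over the list alone (median -0.83, 0.087). Of 15 C1q genes C1qb and Axl fell, 7 adjusted over the list alone (median -0.84, 0.131). Saa3 (4.68 ± 1.24, 0.119), Nos2 (3.28 ± 0.88, 0.119), Ccl5 (2.27 ± 0.54, 0.0874), and Asb2 (-2.26, 0.183) did not pass. Nor did Fcrls (-1.85, 0.186), Cd274 (1.35 ± 0.36, 0.0999), Ctla4 (3.01 ± 0.86, 0.121) and Cd40 (0.89 ± 0.50, 0.463). Apart from AY036118, 20 genes rose and 18 fell (39 called with it, 176 with DESeq2, 20 with at least 20 cells per library). The count of 39 was 14 without untreated replicate 2, and 20, 18 and 20 without ICB replicates 2, 3 and 4. It was 24 without CD40 replicate 2, and 20 and 22 without CD40ICB a replicates 3 and 4. In pooled b, Ly6i had 762 CPM (log2 6.01), Nos2 349 (4.20), Ass1 696 (4.31), Saa3 232 (3.09), Ccl5 859.7 (2.22), Cd274 295 (1.89) and Cd40 67.4 (1.35). Apoe had 5530.2 (-1.89), C1qb 1225 (-1.58), Fcrls 1.85 (-4.11), Asb2 0.924 (-2.68) and Zmynd15 26.2 (-1.84). The interferon-gamma list median was 1.08 (percentile 100). The Chil3 and Lyz2 cluster held 98.4% of the class in b, 43.9% in CD40ICB a and 14.9% in untreated, and the Apoe and C1qa cluster 0.716%, 16.8% and 60.6%.

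Regulatory T-like cells were nearly lacking with the combination, at 1.30% ± 1.13 of T-like cells in CD40ICB a (n = 3, edgeR log2 -4.02 ± 0.82, adjusted p = 5.38e-05) and 1.89% in b (exact 95% interval 1.45 to 2.41). Exact 2-sided permutation gave p = 0.2 for CD40ICB a, the smallest that 2 against 3 libraries allow. Foxp3 (ENSMUSG00000039521, mm10 chromosome X, 7573644 to 7595245, plus strand) fell from 133 ± 38.8 CPM (n = 2) to 2.03 ± 3.51 (n = 3, -4.61 ± 0.88, adjusted p = 0.0416). Il2ra fell by 2.39 ± 0.48 (0.0331), Ikzf2 by 2.51 ± 0.33 (0.000559) and Ikzf4 by 3.05 ± 0.36 (2.23e-05). Tnfrsf18, the GITR receptor of regulatory cells (-1.22 ± 0.25, 0.00871), Klrg1 (-2.92 ± 0.51, 0.00905), Ccr4 (-2.59, 0.0466), and Ttn (-4.46 ± 0.55, 8.96e-05) fell. Itgae fell too (-2.95 ± 0.53, 0.0188, and at most 0.253 without untreated replicate 4 or CD40ICB a replicate 1 or 4). Cxcr3 (1.61 ± 0.32, 0.00751), the interleukin-18 receptor chain Il18rap (1.49 ± 0.35, 0.0331), Cd226 (1.43, 0.0275), Nr4a3 (2.09, 0.0402), and Dusp2 (2.38 ± 0.37, 0.00344) rose. The histone gene Hist1h2ap rose as well (4.11 ± 0.61, 0.00249, and 0.065 without untreated replicate 3). Of 12 regulatory T genes Ikzf2, Itgae, Il2ra and Foxp3 fell, 4 adjusted over the list alone (median -0.90, adjusted p = 0.0115 with an estimated correlation). Of 10 T helper 1 genes Cxcr3 and Il18rap rose, 3 adjusted over the list alone (median 1.33, 0.011). Transcripts of C1q genes, from macrophages, were lower in these T-like droplets, with none of 7 past the threshold, 1 higher and 5 lower adjusted over the list alone and a median of -1.69 (0.0424 with an estimated correlation).

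In the same cells Ifng, the interferon-gamma gene (2.39 ± 1.48, 0.661), the T helper 1 factor Tbx21 (1.86 ± 0.55, 0.138), Tagap (2.92 ± 0.75, 0.105), and Gzmc (-5.55, 0.376) did not pass. Neither did Car2 (-3.80 ± 1.004, 0.155), Pdcd1 (0.60 ± 0.29, 0.494) and Cd40lg (1.21 ± 0.67, 0.597). Ctla4 had 285 ± 12.7 CPM against 311 ± 74.8. CD8 T-like cells made up 57.1% ± 4.40 (log2 0.86 ± 0.59, 0.263) but 7.46% in b, where CD4 conventional cells made up 48.3%. A sub-cluster named naive-like, with Cd8b1 and Ccl5 among its top genes, was not counted as CD8. It held 14 of 296 T-like cells in CD40ICB a and 511 of 3285 in b. The CD8 share of CD40ICB a was past the threshold at 2.65 with a higher Leiden resolution, 2.55 with doublets kept and 0.93 by the cells' own UMIs. CD4 conventional cells rose to 11.0% in CD40ICB a (2.52 ± 0.97, 0.0349), a change that turned to -0.91 by the cells' own UMIs and to -0.51 with Leiden resolution 0.5. Without untreated replicate 4 it was 1.503 (adjusted p = 0.407), and without CD40ICB a replicate 1 or 3 it also missed the threshold. The CD4 cells of both matrices differ, as 838 and 734 of 1586 in b came from sub-clusters that gave 12 and 0 of 25 in CD40ICB a. No gamma-delta T-like cell was seen among 296 T-like cells of CD40ICB a, which at 3 counts of the total allows a share of up to 1.01%, against 2.21% in untreated. Of 6098 genes, 16 rose and 45 fell apart from AY036118 (62 called with it, 62 with DESeq2). The count of 62 was 29 without untreated replicate 4 and 22 without CD40ICB a replicate 4, the library with 61.5% T-like cells. In pooled b, Ctla4 had 741 CPM (log2 1.26), Cxcr3 181 (2.35), Ifng 630.2 (1.97), Il18rap 212 (2.18), Dusp2 698 (2.55), Cd40lg 70.3 (1.58) and Pdcd1 246 (0.585). Foxp3 had 16.7 (-2.30), Itgae 5.10 (-3.62), Gzmc 3.73 (-4.49) and Car2 3.83 (-3.35). Pooled, the CD8 cluster held 77.0% of T-like cells in CD40ICB a and 23.4% in b, and a CD4 cluster 12.7% and 70.4%.

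**Figure D4:**
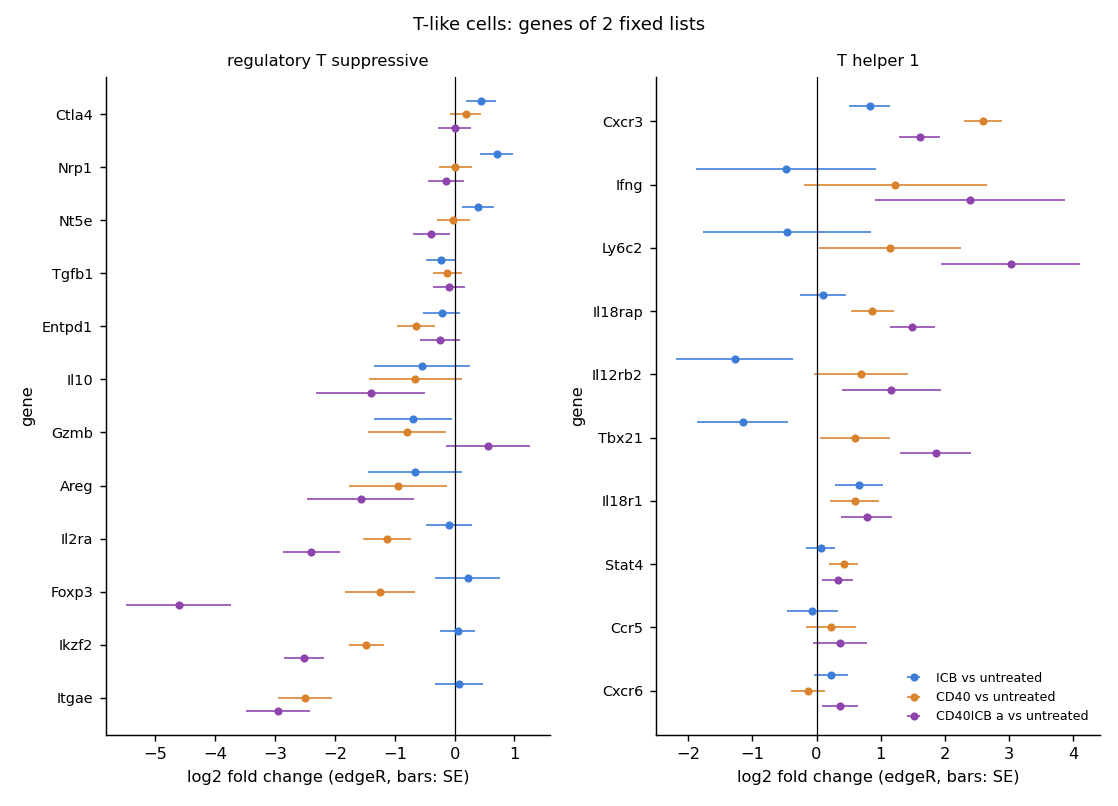
Log2 fold change against untreated (edgeR, bars are SE) of each measured regulatory T gene and T helper 1 gene in T-like cells, for ICB, CD40 and CD40ICB a. Foxp3, Il2ra, Ikzf2 and Itgae lie lowest in CD40ICB a, and Cxcr3 lies highest with CD40.

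CD40ICB a was set against ICB to ask what the agonist added to checkpoint antibodies. In neutrophil-like cells Gbp4 rose by log2 3.11 ± 0.46 (adjusted p = 0.000805) and H2-K1 by 1.98 ± 0.34 (0.00181). Cd274 rose from 225 ± 29.3 to 776 ± 504 CPM (n = 4 and 4, 2.08 ± 0.42, 0.0117). Further rises were Nos2 by 2.20 ± 0.50, Ccl2 by 4.49 ± 0.98 (0.0341), Irf1 by 2.03 ± 0.44 (0.0228) and Cxcl9 by 1.83 ± 0.47 (0.0446). Of 24 interferon-gamma response genes 18 rose, 24 adjusted over the list alone (median 2.18, adjusted p = 0.00407 with an estimated correlation). The same values were 11, 19, 2.001 and 0.0283 for 19 type I interferon genes and 9, 10, 0.94 and 0.00879 for 18 MHC class I genes. Of 13 mitochondrially encoded RNAs 5 fell, mt-Nd3 by 1.51 ± 0.29 and mt-Nd1 by 1.46 among them, 12 adjusted over the list alone (median -1.10, 0.0364). Of 23 hypoxia and glycolysis genes Pfkl rose by 1.06 ± 0.27, 15 adjusted over the list alone (0.82, adjusted p = 0.181 with an estimated correlation). In all 119 genes rose and 20 fell besides sex-linked ones and AY036118 (144 called with them, 265 with DESeq2). The count of 144 was 92, 70, 95 and 59 without ICB replicates 1 to 4, and 44 and 85 without CD40ICB a replicates 3 and 4. Of genes in monocyte/macrophage-like cells 7 rose and 4 fell, with H2-K1 at 0.97 ± 0.16 (0.00709) and Axl at -0.92 (0.0362). Not past the threshold were Cd274 at 1.22 ± 0.36 (0.219) and Cd40 at 1.08 ± 0.50 (0.524). Their interferon-gamma list gave 1 gene, 18 adjusted over the list alone (median 1.29, adjusted p = 0.059 with an estimated correlation). The 16 called there became 39 without untreated replicate 2, and 8, 10 and 8 without ICB replicates 1, 3 and 4. The count was 27, 7 and 9 without CD40ICB a replicates 2, 3 and 4, and 75 with DESeq2.

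In T-like cells of CD40ICB a against ICB, Foxp3 fell from 153 ± 70 to 2.03 ± 3.51 CPM (n = 4 and 3, log2 -4.83 ± 0.83, adjusted p = 0.0118), Ikzf2 by 2.56 ± 0.31 (9.11e-05) and Klrg1 by 3.07 (0.00146). Tbx21 rose from 7.04 ± 4.81 to 59.7 ± 47.2 (3.01 ± 0.56, 0.00313). Cd8a, the CD8 alpha chain, rose from 305 ± 94.8 to 660.0 ± 61.7 (1.25 ± 0.23, 0.00238). Regulatory T-like cells fell from 29.7% to 1.30% of T-like cells (-4.07 ± 0.77, 1.19e-05). CD8 T-like cells rose from 26.8% to 57.1% (1.12 ± 0.50, 0.0377), but 56 of 87 with ICB came from the Gzmc sub-cluster and 113 of 176 in CD40ICB a from the Ret sub-cluster. Naive-like cells rose from 0.593% to 4.28% (3.03 ± 1.03, 0.0108, on 2 and 14 cells). CD4 conventional cells rose (1.91 ± 0.75, 0.0223), and gamma-delta cells fell from 8.26% ± 7.27 to 0 (0 of 296 cells, adjusted p = 2.90e-05), with 36 of the 44 ICB cells from replicate 1 (18.8% there, 3.03% to 7.55% in the others). Of 12 regulatory T genes 4 fell, 6 adjusted over the list alone (median -0.86, adjusted p = 0.0193 with an estimated correlation). Of 10 T helper 1 genes Tbx21 and Il18rap rose, 5 adjusted over the list alone (1.09, 0.0193). Of 20 cytotoxic genes Ctsw rose and Klrg1 and Gzmd fell (median 0.88, 0.223). Of 28 proliferation genes Rrm2 rose (0.92, 0.306). C1q transcripts in these droplets fell, 2 of 7 (median -2.13, 0.0193). Pdcd1 (0.42 ± 0.25), Ctla4 (-0.44 ± 0.23, 0.396), Cd40lg (0.91 ± 0.57) and Cxcr3 (0.78 ± 0.26, 0.106) did not pass. Apart from sex-linked genes and AY036118, 62 rose and 108 fell (176 called with them, 158 with DESeq2). The count of 176 was 80 without ICB replicate 1 and 41 without CD40ICB a replicate 4.

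CD40ICB a was also set against CD40, to ask what checkpoint antibodies added to the agonist. T-like cells gave more genes than neutrophil-like or monocyte/macrophage-like cells. The cell-cycle genes Ccnb2 (log2 3.11 ± 0.53, adjusted p = 0.00232), Rrm2 (2.02 ± 0.36, 0.00260) and Cdca3 (3.31, 0.0433) rose. So did Cd8a (from 282 ± 92.6 to 660.0 ± 61.7 CPM, n = 4 and 3, 1.22 ± 0.23, 0.00868) and Cd8b1 (0.98, 0.0458). A cluster of dividing T-like cells held 0.988% of the class with CD40, 8.61% in CD40ICB a and 12.5% in untreated, and these levels are not independent of it. Before mixed sub-clusters were left out it held 103 of 1991, 51 of 296 and 35 of 200 cells. Cd226 (1.504, 0.00479), Cd160 (2.49 ± 0.43, 0.0228), Cd244 (2.68 ± 0.60, 0.0385) and Klrc2 (1.73, 0.00583), receptor genes picked after their values were seen, rose. Cxcr3 (-0.99 ± 0.23, 0.0433) and Ret (-2.83, 0.0247) fell. Cxcr3 is X-linked, and CD40ICB a and CD40 differ in sex markers, so its fall cannot be told apart from that difference. Regulatory T-like cells fell from 8.47% to 1.30% (-2.15 ± 0.83, 0.0435). Of 28 proliferation genes Ccnb2 and Rrm2 rose, 12 adjusted over the list alone (median 1.58, camera adjusted p = 6.58e-18, adjusted p = 0.185 with an estimated correlation). Of 13 inhibitory receptor genes Cd160 and Cd244 rose, 5 adjusted over the list alone (0.79, 0.185). Cd160, Cd244 and Cd8a are among the top genes of the Gzmc sub-cluster, so their levels are not independent of its share. It held 29 of 1991 T-like cells with CD40, 55 of 296 in CD40ICB a and 48 of 200 in untreated. Apart from sex-linked genes and AY036118, 20 rose and 11 fell (37 called with them, 42 with DESeq2). The count of 37 was 18 and 15 without CD40 replicates 1 and 4. Neutrophil-like cells gave 4 genes, 3 sex-linked and AY036118 (309 at an unadjusted p under 0.05, DESeq2 5), with Cd274 at 0.86 ± 0.41 (0.962). Monocyte/macrophage-like cells gave 5, of which Bnip3, a hypoxia-induced mitophagy receptor, is neither sex-linked nor tied to the reference (1.57 ± 0.29, 0.0467). The count was 3 without CD40 replicate 4 or CD40ICB a replicate 2 or 3 and 9 with DESeq2. Cd40 in these cells gave 0.31 ± 0.52 and Cd274 0.11 ± 0.38. In T-like cells Pdcd1 gave 0.11 ± 0.24, Ctla4 -0.19 ± 0.24 and Cd40lg -0.27 ± 0.50.

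CD40 was set against ICB as a comparison added after the data were seen, since both carry the same sex markers and were counted on the same reference. Neutrophil-like cells had more Gbp4 (log2 2.98 ± 0.41, adjusted p = 0.000752), H2-K1 (1.81, 0.00498), Isg15 (1.92, 0.00464), Tap1 (1.83, 0.00138) and Cxcl9 (1.89, 0.0168) with CD40. They had less Selenop (-2.31 ± 0.43, 0.0078), Cd81 (-1.02, 0.0291) and mt-Nd6 (-1.19, 0.0247). Of 24 interferon-gamma response genes 19 rose, 24 adjusted over the list alone (median 1.90, adjusted p = 0.00109 with an estimated correlation). The same values were 7, 18, 1.53 and 0.0431 for 19 type I interferon genes and 9, 13, 1.17 and 0.00569 for 18 MHC class I genes. Of C1q genes 2 fell (median -1.63, 0.116). Whether the falls of such macrophage genes come from macrophage RNA in the droplets was not tested. In all 62 genes rose and 24 fell. Monocyte/macrophage-like cells gave 0 genes with edgeR, 388 at an unadjusted p under 0.05 and 13 with DESeq2. Their interferon-gamma genes had a median of 1.24, with 24 higher when adjusted over the list alone (adjusted p = 0.0222 with an estimated correlation). Their macrophage subset fell from 27.6% to 11.2% (-1.22 ± 0.13, 8.54e-07). In T-like cells Cxcr3 rose (1.77 ± 0.23, 4.01e-05). Ikzf2 (-1.53 ± 0.26, 0.00392), Ikzf4 (-2.80 ± 0.30, 2.03e-06), Itgae (-2.58, 0.0063) and Ccnb2 (-2.79, 0.00203) fell, and Foxp3 gave -1.46 (0.243). Regulatory T-like cells fell from 29.7% to 8.47% of T-like cells (-1.93 ± 0.53, 0.002). Gamma-delta cells fell from 8.26% ± 7.27 to 1.40% of T-like cells (-2.46 ± 0.64, 0.00188, with 36 of the 44 ICB cells from replicate 1). The T-like count was 62 higher and 77 lower.

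Whether the combination differed from the product of both single-agent effects was tested as an interaction in CD40ICB a. In T-like cells Cxcr3 was lower than that product (log2 -1.82 ± 0.40, adjusted p = 0.0283), as were Cited2 (-2.06, 0.00254) and Cysltr1, a leukotriene receptor (-4.83, 0.0101). Cd8a (1.939 ± 0.34, 0.00579), Cd8b1 (1.63, 0.0274), Rrm2 (2.78 ± 0.55, 0.0101), Cd244 (3.49, 0.0307) and Klrc2 (2.29, 0.035) were higher. Cd8a and Cd244 are among the top genes of the Gzmc sub-cluster, so their terms are not independent of its share. Of 28 proliferation genes Rrm2 was higher, 2 adjusted over the list alone (median 1.72, camera adjusted p = 1.12e-14, adjusted p = 0.298 with an estimated correlation). The term was past the threshold for 31 genes (30 with DESeq2), 16 higher and 9 lower besides sex-linked ones and AY036118. It was past it for 10 without untreated replicate 3, 17 without ICB replicate 1, 18 without CD40 replicate 4 and 17 without CD40ICB a replicate 4. Regulatory T-like cells gave -2.20 ± 1.01 (0.118), and 0.29 with a higher Leiden resolution. Neutrophil-like cells gave 6 genes (11 with DESeq2), of which the chemokine receptor Ccr2 (-6.40 ± 1.22, 0.0384) is neither sex-linked nor tied to the reference. Ccr2 was low in these droplets, at 5.41 CPM in untreated and 26.5 with CD40, against 224 in monocyte/macrophage-like cells with CD40. Whether RNA of those cells in the droplets has a part in the Ccr2 term was not tested. Monocyte/macrophage-like cells gave 5, all sex-linked (8 with DESeq2). Since sex markers match in untreated and CD40ICB a and differ in both single-agent groups, this term carries that difference as well. In summed counts the interferon-gamma list of neutrophil-like cells gave 0.448 over the mean of both CD40ICB matrices, -0.214 for CD40ICB a and 1.11 for CD40ICB b.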

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

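Single libraries stood apart from the rest of their group in cell shares and in several named genes, by Dixon's ratio of the gap to the range. The ratio marks about 1 group in 20 by chance, and of 280 groups tested 50 met it where 14 would by chance. That number holds for normally spread values. A value seen in only 1 library of a group gives a ratio of 1.0 whatever its size, so the excess is partly built in. Replicate 4 of CD40 held 65.0% T-like cells (ratio 0.912) and 0.0373% tumour-like cells, and replicate 4 of CD40ICB a 61.5% T-like cells (0.84). The same CD40ICB a library led its group in NK cells (6.37%, ratio 0.887), B cells (0.277%, ratio 1.0) and the monocyte subset (17.9%, ratio 0.873). The group held 1 B cell and 6 cells of the monocyte subset in all, so these 2 ratios say little.

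In neutrophil-like cells the T-cell chemokine gene Ccl5 was led by ICB replicate 1 (357 CPM, ratio 0.952) and by CD40 replicate 4 (1822, ratio 0.905), and Apoe was lowest in CD40ICB a replicate 3 (161, ratio 0.831). Saa3 was led by untreated replicate 3 (637.5, ratio 0.974), Ly6i by CD40 replicate 3 (230.7, ratio 0.937), Cx3cr1 by CD40ICB a replicate 4 (177, ratio 0.839), Gadd45g by ICB replicate 3 (54.1, ratio 0.83) and H2-Q7 by ICB replicate 1 (44.5, ratio 0.841). Lymphocyte receptor genes were near 0 with 1 library above: Cd40lg in untreated, ICB and CD40 (ratio 1.0 each), Ctla4 in CD40ICB a (1.0), and Pdcd1 in untreated, ICB and CD40ICB a (1.0 each) and CD40 (0.894).

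In monocyte/macrophage-like cells the mast-cell proteases were led by 1 library in the groups named here. Mcpt1 and Mcpt2 had ratios of 0.971 and 0.968 in untreated (replicate 2), 0.996 each with ICB (replicate 4; 419 and 629 CPM) and 1.0 each in CD40ICB a (replicate 4), and Cma2 1.0 in untreated and 1.0 with ICB (replicate 4; 235.5 CPM). Granzymes did likewise: Gzma in untreated (replicate 4, 1249 CPM, ratio 1.0), ICB (0.951) and CD40ICB a (replicate 1, 588 CPM, ratio 0.903), and Gzmf in untreated (replicate 4, 373 CPM, ratio 0.986) and ICB (1.0). Ass1 was led by untreated replicate 3 (68.2, ratio 0.923), Ccl7 by CD40ICB a replicate 2 (807, ratio 0.86), Retnla by untreated replicate 4 (0.904) and CD40ICB a replicate 1 (269, ratio 0.936), and Zmynd15 was lowest in ICB replicate 3 (68.4, ratio 0.885). Cd40lg was seen in 1 library of untreated and of CD40ICB a (1.0 each), and Pdcd1 stood apart in untreated (0.897) and CD40ICB a (0.882).

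In T-like cells Ifng was led by CD40 replicate 3 (1224 CPM, ratio 0.846), which also led Cd40lg (178, ratio 0.84) and Cst3 (306, ratio 0.889). Gzma was led by CD40 replicate 4 (382, ratio 0.935), Gzmc by ICB replicate 2 (398, ratio 0.926), and Gzmf by ICB replicate 1 (ratio 0.837) and CD40 replicate 4 (1.0).

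The effect of CD40 differed with and without ICB for 6 genes in neutrophil-like, 5 in monocyte/macrophage-like and 31 in T-like cells, sex-linked genes included, and for the gamma-delta T share (log2 -7.05). That fold depends on the prior count added to the 0 cells of CD40ICB a and is no bound. UMIs on human genes numbered 5593 in CD40ICB a (0.0451%) and 7434 in b (0.0182%), and what they come from was not examined.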

How the results depend on the processing

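The alternatives were fixed before the data were examined except for those named as added, which were chosen only after results had been seen. The cause of each difference given here was not tested. Of 67 leading results 18 stayed the same throughout, and of the named genes and lists 110 did. No paired analysis was possible because the suffixes carry no replicate number shared across groups.

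The CD4 conventional share was the least stable T-cell result. Against untreated it gave log2 2.73 with CD40 and 2.52 in CD40ICB a, but -0.14 and -0.51 at Leiden resolution 0.5 and -0.27 and -0.91 by the cells' own thinned UMIs, where ICB gave -0.16 in place of 0.61. Clustering without subset markers, an added alternative, gave 5.60 (adjusted p = 0.293) and 6.16 (0.131). Without untreated replicate 4 it gave 1.71 and 1.503, neither past the threshold, and -0.41 with ICB. In CD40ICB a it also missed the threshold without CD40ICB a replicate 1 or 3 (2.48 and 2.36). Without untreated replicate 3 the share gave 7.68, 7.47 and 5.56.

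The CD8 share passed the threshold only under some settings. With CD40 and in CD40ICB a it gave 0.78 and 0.86, and 3.58 and 2.65 at resolution 2.0, 2.96 and 2.55 with doublets kept, and 0.93 in CD40ICB a by own UMIs, all past the threshold. With ICB it gave -0.26, but 0.70 at resolution 2.0, and -0.65 to 0.27 over fits without 1 library, the highest without untreated replicate 3 and the lowest without replicate 4.

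The regulatory T share with CD40 was -1.87, and ran from -2.31 without untreated replicate 3 to -1.22 (adjusted p = 0.421) without replicate 4. With ICB it was 0.05, -0.14 at resolution 2.0, and -0.39 to 0.71 without untreated replicate 3 or 4. The combination against both agents gave -2.20, 0.29 at resolution 2.0, and -2.86 to -1.76 without untreated replicate 4 or 3.

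The macrophage share fell with CD40 (-0.99) and in CD40ICB a (-1.67), but at resolution 0.5 gave -0.0114 and 0.58, and with ICB -0.52 in place of 0.22. With doublets kept ICB gave -0.0936. The monocyte/macrophage share of all cells gave -0.19 with ICB, -1.38 with CD40 and -1.51 in CD40ICB a, but 0.25, 0.66 and 0.51 when each library was clustered on its own. Leaving out 1 library gave -0.41 to 0.21 with ICB (without untreated replicate 1 or 2) and -1.72, past the threshold, to -1.11 in CD40ICB a. Without non-immune cells it gave -1.31 in CD40ICB a, past the threshold.

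The T share of CD40ICB a was 2.13, 2.004, past the threshold, without non-immune cells and -0.66 with each library clustered on its own. The combination against both agents gave -0.89, from -2.46 without CD40ICB a replicate 4 to 0.36 without CD40 replicate 4. The neutrophil share of CD40ICB a was 0.24, -0.0442 with each library clustered on its own, and -0.30 to 0.60 without CD40ICB a replicate 2 or 4.

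DESeq2 in place of edgeR gave more genes in neutrophil-like cells of CD40ICB a against untreated (75, from 41) and ICB (265, from 144) and for the combination against both agents (11, from 6). In monocyte/macrophage-like cells it gave 43 for CD40 (from 10), 176 for CD40ICB a (from 39), 75 against ICB (from 16), 9 against CD40 (from 5) and 8 for the combination (from 5). In T-like cells with CD40 it gave 58, from 94.

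Without the filter on low genes, T-like cells gave 7 genes for ICB (from 4), 186 for CD40 (from 94), 129 for CD40ICB a (from 62), 281 against ICB (from 176), 79 against CD40 (from 37) and 54 for the combination (from 31). Neutrophil-like cells gave 7 for CD40ICB a against CD40 (from 4) and monocyte/macrophage-like cells 16 for CD40 (from 10).

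Pooled CD40ICB b differed from untreated at least 2-fold in 981 neutrophil, 482 monocyte/macrophage and 297 T genes. With no minimum CPM the counts were 1556, 784 and 484, and with its wells as libraries in edgeR, an added alternative, 3623, 2518 and 1300 genes passed. The interferon-gamma median of its neutrophil-like cells was 2.637 in summed counts, 3.143 with TMM, 2.271 with no minimum CPM and 2.889 with a pseudocount of 1 CPM. Over both matrices it was 1.975, with 1.313 for CD40ICB a and 2.637 for b alone. The combination over both agents gave 0.448, 0.862 with TMM, -0.214 for a and 1.11 for b. The matrices also parted in neutrophil share (mean 43.26%, a 21.59%, b 64.92%) and T-cell Ctla4 (log2 mean 0.605, a -0.049, b 1.259). Their CD8 shares of T-like cells were 59.46% in a and 7.458% in b (mean 33.46%), without the naive-like sub-cluster. That sub-cluster had Cd8b1 among its top genes and held 4.73% of T-like cells in a and 15.56% in b.

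List medians near 0 changed sign. For the interferon-gamma list in neutrophil-like cells, ICB gave -0.104, and 0.012 with total counts in place of TMM; the type I interferon list gave -0.13 and 0.033. CD40ICB a against CD40 gave 0.108, -0.018 with total counts and -0.248 at 1000 UMIs per cell. The combination gave 0.209, -0.049 with total counts and -0.018 with no filter on low genes.

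In monocyte/macrophage-like cells the interferon-gamma list gave -0.182 for ICB (camera adjusted p = 0.00121), 0.0 with doublets kept and -0.186 (0.247) at 1000 UMIs. CD40ICB a against CD40 gave 0.027, -0.026 with total counts, -0.055 with no filter and -0.155 at 1000 UMIs, and the combination 0.156 and -0.072 at 1000 UMIs. The MHC class I list for ICB gave -0.005, 0.03 with total counts, 0.147 with doublets kept and 0.022 at 1000 UMIs. The hypoxia list gave -0.042 for ICB and 0.062 with doublets kept, and for CD40 -0.026, 0.006 with total counts, 0.034 with doublets kept and 0.073 at 1000 UMIs.

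In T-like cells the T helper 1 list for ICB gave -0.003, 0.028 with total counts, 0.036 with no filter, 0.028 with doublets kept and 0.438 at 1000 UMIs. The regulatory T list for ICB gave -0.022, 0.033 with no filter and 0.067 with doublets kept. With CD40 and no filter the interferon-gamma list gave 0.024, from -0.054, and the cytotoxic list 0.284, from -0.13.

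A minimum of 20 cells per library, an added alternative, gave 27 genes for CD40ICB a in neutrophil-like cells and 20 in monocyte/macrophage-like cells, in place of 41 and 39. Leaving out 1 library also moved the gene counts. In neutrophil-like cells CD40 gave 19 (without untreated replicate 4) to 84 (CD40ICB a replicate 3), CD40ICB a 18 (untreated 4) to 66 (CD40ICB a 1), and CD40ICB a against ICB 44 (CD40ICB a 3) to 197 (untreated 3). In monocyte/macrophage-like cells ICB gave 3 to 6, CD40 4 (CD40 4) to 17 (CD40ICB a 4), CD40ICB a 14 (untreated 2) to 56 (untreated 1), CD40ICB a against ICB 7 (CD40ICB a 3) to 39 (untreated 2) and against CD40 3 to 6. In T-like cells ICB gave 4 to 7, CD40 32 (CD40 4) to 127 (CD40ICB a 3), CD40ICB a 22 (CD40ICB a 4) to 69 (CD40 4), against ICB 41 (CD40ICB a 4) to 201 (ICB 2), against CD40 15 (CD40 4) to 48 (untreated 3), and the combination 10 (untreated 3) to 38 (ICB 3).

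Interferon-gamma medians over those fits ran in neutrophil-like cells from -0.334 to 0.02 for ICB, 1.697 to 2.031 for CD40, 1.656 to 2.306 for CD40ICB a, -0.071 to 0.271 against CD40 and -0.079 to 0.438 for the combination. In monocyte/macrophage-like cells they ran from 0.775 to 1.199 for CD40, 0.835 to 1.402 for CD40ICB a, -0.305 to 0.275 against CD40 and -0.081 to 0.406 for the combination. The lowest of the medians under 0 against CD40 and for the combination came without CD40ICB a replicate 3 in neutrophil-like cells and replicate 4 in monocyte/macrophage-like cells.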

Other observations

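The tests weighed in this part, apart from the fits without 1 library, were chosen only after the results had been seen.

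A cluster led by Mmp12, Arg1, Pf4, Mmp13 and Ccl24, genes of tissue-remodelling macrophages, held 17.9% of untreated cells and 11.6% with CD40. With CD40 its Psmb9, an immunoproteasome gene, rose (log2 1.12 ± 0.22; edgeR adjusted p = 0.000779) while 12 of 13 mitochondrially encoded RNAs fell (median -1.24; 0.00119 with an estimated correlation), and Arg1 stayed at 2794 ± 617 and 2827 ± 733. Chil1 (3.58 ± 0.75), Plet1 (3.36 ± 0.50) and Ly6a (2.83 ± 0.57) rose. Tumour-like epithelial cells of CD40ICB a against ICB had more Cxcl10 (5.16 ± 0.85; 0.0129), Irf1 (1.87 ± 0.27; 0.00294) and Cd274 (2.85 ± 0.63; 0.0258), and less Krt8 (-0.80 ± 0.15; 0.00948), with 12 of 28 interferon-gamma genes higher (median 2.85; 0.111 with an estimated correlation). These cells carried Xist at 844 to 2743 CPM in every group.

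Interferon-gamma response genes were higher with CD40 in neutrophil-like cells, and in monocyte/macrophage-like cells with a preset correlation only (adjusted p = 0.0813 with an estimated one). Sex as the cause is argued against by CD40 against ICB, alike in sex markers, which kept an interferon-gamma median of at least 1.244 in both classes. A single library is argued against by a lowest median of 0.775 over fits without 1 library, and macrophage RNA in neutrophil-like droplets by a rise of 124% of the level in macrophages (median, 73.3% for MHC class I genes), whose abundant markers were seen there at 8.98% at most. CD40ICB a against ICB gave interferon-gamma medians of at least 1.289, as the agonist as cause would need, but differs in sex markers and reference too, with an adjusted p of 0.059 in monocyte/macrophage-like cells by an estimated correlation. The bound first set was the upper quartile of all macrophage markers (33.7%). It left the MHC class I genes, with a median of 73.3% and a lower quartile of 30.2%, open. The 8.98% replaced it after both values had been seen, so for these genes the test decides nothing. Interferon-gamma genes, with a lower quartile of 61.2%, lie above both bounds.

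The CD40ICB matrices differed from each other in 683 neutrophil genes of at least 2-fold. The gene reference is argued against by a difference of 0 features between them. A sex difference present without the agonist is argued against by 21 genes between ICB and untreated, which differ in sex markers in the same way. Neither of those groups received the agonist, so a response to the combination that differs by sex cannot be weighed by them. A batch of libraries cannot be told apart from any other difference between the matrices, because matrix and batch coincide. Which matrix is closer to the effect of the combination stays open.

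Libraries were regrouped in every balanced split, 35 per comparison, to see how often as many genes passed. In neutrophil-like cells 1 split, the real one, reached the count for ICB (4, highest other 1), CD40 (55, other 1), CD40ICB a against ICB (144, other 1) and CD40 against ICB (86, other 2). For CD40ICB a against untreated 2 splits did (41, other 52), and for CD40ICB a against CD40 2 (4, other 18), so a structure of samples other than treatment could give as many genes there. In monocyte/macrophage-like cells 1 split did for ICB (5, other 1), CD40 (10, other 1), CD40ICB a (39, other 8), CD40ICB a against ICB (16, other 0) and against CD40 (5, other 1), and 35 for CD40 against ICB (0, other 0). The genes of ICB were all sex-linked in both classes, and since the groups differ in sex markers in every library that split had to lead and says nothing of treatment. The same holds for 3 of the 4 genes of CD40ICB a against CD40 in neutrophil-like cells and 3 of the 5 in monocyte/macrophage-like cells, and AY036118, which may follow the gene reference, is another in each.

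In T-like cells 1 split reached the count for CD40ICB a against ICB (176, other 46) and CD40 (37, other 15). The same held for CD40 against ICB (139, other 5). Untreated had only 2 libraries with enough T-like cells, so no splits were run against it and those T-like counts lack this check. In the Arg1 cluster 8 splits did for ICB (1, other 3), where other structure gave more genes, and 1 for CD40 (70, other 7), CD40ICB a (26, other 3), CD40ICB a against ICB (27, other 1) and CD40 (2, other 1), and CD40 against ICB (31, other 3). The 2 genes of CD40ICB a against CD40 there are Eif2s3y, on the Y chromosome, and AY036118, so that split decides nothing either. In tumour-like cells 1 split did for ICB (2, other 0) and CD40ICB a against ICB (653, other 0). For CD40ICB a against untreated there are 10 splits, too few (33, other 2).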
